A study of Mus musculus with 4 samples.

How the data were processed

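Kidney RNA from mice of the inbred strains C57BL/6 and FVB/N was measured on Illumina mouse bead arrays, in diabetic and saline-injected control animals. Per the labels, total RNA was extracted with Trizol, cleaned on columns with DNase treatment, checked on a Bioanalyser, and turned into biotinylated cRNA that was stained with streptavidin-Cy3. The series text gives 6 kidneys per group, mice of both sexes at 8 weeks of age, and tissue collected at 1 time for all groups; the labels give 21 days of diabetes or of control treatment. Each of the 4 groups has 1 column of values, called a library here, and whether that column is a pool of the group's 6 kidneys or 1 kidney of them is not given in the sources used here. How diabetes was induced is not given either.

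The deposited values are read as log2 intensities. They ran from 4.45 to 15.84 across the 4 libraries, the range of an array scanner on a log2 scale. The medians were 5.48 in the C57BL/6 diabetic, 5.48 in the C57BL/6 control, 5.49 in the FVB/N diabetic and 5.48 in the FVB/N control library. After each library was sorted by value, the libraries differed by at most 0.42 log2 at any rank and by a median of 0.0029, and between 47.1% and 59.0% of a library's values occurred again in another library. Such near-identical distributions follow quantile normalization between arrays, but the normalization method, the background correction and any filtering by the authors are not given in the sources used here. Detection calls are not part of the values used, so a value near the bottom of the range is described as near background. The small number of arrays, 1 per group, limits the precision of every value.

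The values were used as they are. Of 24613 probes, 20985 were in the probe annotation and 20984 had exactly 1 gene symbol; 1 probe with several symbols was left out, as were 3628 probes without an annotated gene, of which 1477 reached the expression minimum as a separate group. Symbols were checked against the reference gene table by gene identifier for 20968 probes, and 0 differed. The named probes covered 15967 genes, 3728 of them with several probes, and each gene was represented by the probe with the highest mean over the 4 libraries. A gene counted as expressed when that mean was at or above 5.49, the median of all probes, which left 9201 genes.

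Every comparison is a difference of log2 values per gene. Diabetes was compared with control within each strain as diabetic minus control, the strains were compared as FVB/N minus C57BL/6 within controls and within diabetics, and the effect of diabetes in C57BL/6 was subtracted from that in FVB/N. Genes at least 2-fold apart, 1 on the log2 scale, were counted in each direction. With 1 library per group there is no spread between replicates, so no test was run and no p-value is given. The correlation of the diabetes differences of the 2 strains, which share no library, was computed across genes, which are not independent replicates, with a bootstrap interval over 1000 resamplings of genes.

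Gene lists were written by hand for kidney and diabetes, 35 of pathways and functions and 22 of cell type markers, 57 in all. For each of the 50 lists with at least 5 expressed members, the median log2 difference was ranked among 10000 random lists of the same size drawn to match its members on mean expression in 20 bins. A list is called outside the random range when its median lay outside the central 95% of those medians. The ranking describes these libraries and is not a test of diabetes or strain, since members of a list are co-regulated and lists share genes; 2.5 of 50 unrelated lists would lie outside by chance. Members were counted as higher or lower when at least 1.5-fold apart. Of all 9201 expressed genes, 565 were higher and 584 lower by this measure in C57BL/6, and 1142 and 1282 in FVB/N. Member counts are to be read against these, and those of the 2 strains are not directly comparable.

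Genes named in the text follow a rule. It takes the 10 genes with the largest difference in each direction in each strain, the 10 in each direction common to both strains by the smaller difference, the 5 in each direction with the largest difference between the strains' effects, and the 10 in each direction with the largest strain difference by the smaller of the control and diabetic values. It adds up to 4 members with the largest difference from each list outside the random range in that strain, up to 3 members of any other list described, all measured genes of the Y chromosome, and Nnt and Hc as strain checks. Gene models without an established name were skipped and not replaced. The 57 lists, the rule, the filter, the threshold and all alternatives but 1 were set before the data were examined.

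The alternatives were quantile normalization of the 4 libraries, centring of each library on its median, loess centring of each difference on intensity with a span of 0.3, no expression filter, a stricter filter at percentile 75 of all probes, the mean of all probes of a gene, an offset of 16 added to the intensities, and a threshold of 1.5-fold. Loess centring on gene length was added after the data had been seen. A further list of adipocyte-restricted markers and a list of p53 targets were added later, for tests of explanations in the closing section.

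The procedure was tested on simulated data made from these libraries, with known differences put into 50 genes per size. Of genes given a log2 difference of 1, 56.0% were counted as at least 2-fold apart in the C57BL/6 setting and 62.0% in the FVB/N setting; at a log2 difference of 1.5 the shares were 86.0% and 78.0%, and at 2 and 3 they were 100% in both. Of 9001 genes given no difference, 188 (2.09%) were counted as at least 2-fold apart in the C57BL/6 setting and 635 (7.05%) in the FVB/N setting, about as many as in the real comparisons, because the simulated noise was the real differences shuffled among probes of like intensity. A count of genes at least 2-fold apart therefore includes noise and any real difference without separating them. Of 200 lists of 15 genes without a difference, 6.5% lay outside the random range in the C57BL/6 setting and 5.5% in the FVB/N setting, and of lists shifted by 0.5 log2, 98.5% and 82.5% lay above it. The lists without a difference were themselves drawn at random from the shuffled values, so a low share outside was built in. It does not give the rate for the lists written by hand, whose members are co-regulated. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6; plots were drawn with matplotlib 3.10.9.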

Results

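Transcript levels were measured in whole kidneys of mice of the inbred strains C57BL/6 and FVB/N, each as a diabetic group and a saline-injected control group. Per the labels, the mice had been diabetic, or treated as controls, for 21 days, and the series asks which genes mark the early kidney response to diabetes on different genetic backgrounds. There were 4 groups with 6 kidneys each and 1 library of array values per group, so no difference below has a replicate check, and each compares 2 libraries. Intensities on the log2 scale ran from 4.45 to 15.84. Of 15967 genes measured, 9201 were expressed above the minimum of 5.49. Across these genes the spread of the differences, as a standard deviation, was 0.39 log2 between the C57BL/6 libraries and 0.55 between the FVB/N libraries. It was 0.49 between the control libraries and 0.68 between the diabetic libraries. Over all probes, the FVB/N diabetic library differed from the others by a median of 0.23 to 0.24 log2, without regard to sign, and the others among themselves by 0.17 to 0.20. For 1372 genes with 2 expressed probes, the diabetes differences of the probes correlated at only 0.30 in C57BL/6 and 0.29 in FVB/N. The standard deviation of a single probe's difference was 0.33 and 0.47 log2, so differences of single genes are imprecise.

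The first comparison asks which kidney genes differed with diabetes in C57BL/6. Lipid-making genes were lower in the diabetic library, with fatty acid synthase, Fasn, at -2.02 log2 and the desaturase Scd1 at -1.62. Higher were the kidney injury molecule Havcr1 at 1.74, the neutrophil chemokine Cxcl1 at 1.96 and the inflammatory caspase Casp4 at 1.86, while the tubular injury list had a median of 0.13, inside the random range, with 4 of 19 members at least 1.5-fold higher and 1 lower. The organic anion efflux pump Abcc3 was 2.72 log2 lower, and angiotensin-converting enzyme, Ace, was 1.63 log2 lower. In total 95 genes were at least 2-fold higher and 91 at least 2-fold lower in the diabetic library, and with the stricter filter 14 and 29.

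The gene with the largest positive difference was Fbxw5, which encodes a substrate receptor of a ubiquitin ligase, at 3.46. Slpi, an inhibitor of leukocyte peptidases, stood at 2.11, and Serpina10, the inhibitor that acts with protein Z in coagulation, at 2.04. The zinc transporter Slc39a8 was 1.85 higher and Aoc1, the diamine oxidase that degrades histamine and putrescine, 1.78 higher. Prc1 and Spag5, which organize the mitotic spindle, were 1.67 and 1.65 higher. On the lower side, the proteasome ATPase Psmc1 stood at -2.29, the latent TGF-beta binding protein Ltbp4 at -1.95 and Styxl1 at -1.87. Cidea, a lipid droplet protein of brown fat, and Cd180, a toll-like receptor relative of B cells and macrophages, were both at -1.81. The adhesion genes Celsr2 and Cadm1 were at -1.76 and -1.65. The C57BL/6 control library alone was high for Ltbp4 and Styxl1, at 7.32 and 6.96, against at most 5.87 and 5.38 elsewhere. For Psmc1, Cidea, Cd180, Celsr2 and Cadm1 the C57BL/6 diabetic library was the lowest of all. Below the expression minimum on the lower side of their difference, so that its size is uncertain, were Havcr1, Slpi, Casp4, Ltbp4, Styxl1, Cidea and Cd180, and among genes given next Cidec, Thrsp, Cry2, Cyp27b1, Cyp7b1, Ccl9 and Il1b. With all probes of a gene averaged, Ace came to -0.86, Celsr2 to -0.73, Ltbp4 to -0.98, Slc39a8 to 1.05 and Spag5 to 0.81, while Casp4 and Styxl1 dropped below the expression minimum.

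Among the lists of related genes, the fatty acid synthesis list had a median of -0.61 in C57BL/6, with 7 of 12 expressed members at least 1.5-fold lower and 0 higher. Besides Fasn and Scd1, the carboxylase Acaca stood at -1.35 and the lipogenic regulator Thrsp at -0.99. The adipocyte list had a median of -0.78, with 8 of 12 members lower, including Ucp1, the uncoupling protein of brown fat, at -1.51, Cidec at -1.003 and the carbonic anhydrase Car3 at -0.99. No random list of matched expression had a median as low as these.

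Several lists of transport, gluconeogenesis and tubule segments had slightly lower medians in the C57BL/6 diabetic library. The loop of Henle list, with a median of 0.18, did not, and lay inside the random range. The amino acid transport list had a median of -0.26, with 0 of 14 members at least 1.5-fold lower and 1 higher. Its transporters Slc6a18 at -0.55 and Slc3a1 at -0.53 were below control, and the lysosomal transporter Slc36a1 at 1.17 was above. The list of glucose, phosphate and organic anion transport had a median of -0.19, with the dicarboxylate transporter Slc13a3 at -1.33, the organic anion transporter Slc22a8 at -0.85 and the glucose transporter Slc5a1 at -0.50. In the gluconeogenesis list, median -0.23, none of 9 members reached 1.5-fold, and Pcx at -0.57, G6pc at -0.56 and Pck1 at -0.48 lay lower. Markers of the proximal tubule's S1 and S2 segments had a median of -0.19, where the nuclear receptor Hnf4a was at -0.64 and the creatine-pathway enzyme Gatm at 1.09. For the S3 segment the median was -0.23, with the organic anion transporter Slc22a7 at -1.16 and the hydroxylase Cyp7b1 at 1.13. The distal convoluted tubule list had a median of -0.33, and the kinase Wnk4, a regulator of salt transport, was its 1 member at least 1.5-fold lower, at -0.71.

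The podocyte and endothelial lists also had lower medians in C57BL/6. Mesangium, pericyte and smooth muscle markers, with a median of -0.15 and 0 of 8 members at least 1.5-fold lower, lay inside the random range. Podocyte markers had a median of -0.40, with 2 of 7 members lower, the matrix protein Npnt at -0.75 and the surface sialoprotein Podxl at -0.66. Endothelial markers had a median of -0.22, with Ehd3 of glomerular endothelium at -0.90 and the cadherin Cdh5 at -0.66 lower among 16 members. The renin-angiotensin list stood at -0.30, with Ace and the aminopeptidase Anpep, at -0.80, lower. Insulin and IGF signalling had a median of -0.25, with the receptor Igf2r at -1.09 and the signalling inhibitor Socs2 at -0.99. Circadian clock genes had a median of -0.27, with the repressors Cry2 at -0.90 and Per2 at -0.63. The calcium, phosphate and vitamin D list had a median of -0.19, but its 3 members beyond 1.5-fold were all higher: the vitamin D hydroxylase Cyp27b1 at 0.88, the exchanger Slc8a1 at 0.74 and the calcium-binding protein S100g at 0.73. In the list of genes with higher expression in female kidneys, median -0.26, Abcc3 was the 1 member of 11 at least 1.5-fold lower, and Napsa stood at -0.50.

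Lists with higher medians in the C57BL/6 diabetic library were those of cell division, inflammation, macrophages, blood, respiration and liver. The cell cycle list had a median of 0.51 with 4 of 13 members at least 1.5-fold higher. They were Prc1, the spindle protein Nusap1 at 1.35, the centromere histone Cenpa at 0.98, and Cdkn1a at 1.52, which inhibits cell division. Inflammation and chemokine genes had a median of 0.33, with Cxcl10 at 1.23, Ccl9 at 1.13 and Il1b at 1.04. Macrophage and dendritic cell markers had a median of 0.39, with the lysozyme Lyz2 at 1.18, the chemokine receptor Cx3cr1 at 0.90, the complement gene C1qc at 0.81 and Aif1 at 0.65. The erythroid list, with 5 members, had a median of 0.73 and included the globin Hbb-b2 at 1.12. Oxidative phosphorylation had a median of 0.19 over 32 members, of which Atp5pb at 0.81, Cox7b at 0.77 and Cox7a2 at 0.64 were at least 1.5-fold higher. Among liver transcripts, median 0.35, the thyroid hormone carrier Ttr was at 0.60 and Apoa2 at 0.48. In total 21 of 50 ranked lists lay outside the central 95% of random lists, 6 above and 15 below, where 2.5 would by chance if lists were unrelated. In at least 1 of 8 alternative settings, 8 of the 21 lay inside it: gluconeogenesis, renin-angiotensin, inflammation, circadian clock, insulin and IGF, calcium, S3 and distal convoluted tubule. Inflammation, for example, was at percentile 93.1 without a filter and 85.5 with the stricter filter.

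The second comparison asks the same question in FVB/N. Serpina6, which encodes corticosteroid-binding globulin, was 4.01 log2 higher in the diabetic library. The cell-cycle inhibitor Cdkn1a was 2.99 higher, the tubular injury marker Lcn2 2.88 higher, and the collecting duct water channels Aqp2 and Aqp3 2.81 and 2.66 higher. The largest falls were those of Ucp1 at -5.27, Car3 at -3.17 and the cytochrome oxidase subunit Cox8b at -2.83. In total 373 genes were at least 2-fold higher and 201 at least 2-fold lower, after loess centring on intensity 481 and 145, and with the stricter filter 160 and 128.

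Other genes high in the FVB/N diabetic library were Eif4ebp3, a repressor of translation, at 2.84, Ogfod2 at 2.61, the fatty acid hydroxylase Cyp4a12a at 2.55 and Pappa, a protease of IGF-binding proteins, at 2.33. Slc6a12, which takes up the osmolyte betaine, was at 2.27. On the lower side, the lipid droplet hydrolase Pnpla3 and Tprg were both at -2.58, the organic anion transporter Slc22a26 at -2.30 and Nrep at -2.13. Itih1, a chain of the inter-alpha-trypsin inhibitor, was at -2.10, the androgen-regulated kidney protein Kap at -2.08 and the growth factor Mdk at -2.05. The FVB/N control library alone was high for Pnpla3, Tprg and Itih1, at 8.71, 8.88 and 9.42, against at most 6.14, 6.44 and 7.32 elsewhere. For Slc22a26, Nrep, Kap and Mdk the FVB/N diabetic library was the lowest of all. Car3 came to -1.69 when its probes were averaged. On the lower side of the difference Serpina6, Aqp3, Pappa and Ucp1, and among genes given next Ugt8a, Mvk and Reg1, were below the expression minimum, so the size of these differences is uncertain.

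Genes of water handling stood out in FVB/N. The water and sodium handling list had a median of 0.21 with 7 of 27 members at least 1.5-fold higher and 0 lower, including Aqp2, Aqp3, Slc6a12 and the kinase Wnk1 at 1.05. Markers of collecting duct principal cells had a median of 0.56 with 5 of 11 members higher, where the glucocorticoid-inactivating enzyme Hsd11b2 was at 1.21 and the transcription factor Elf5 at 1.20. Both lists hold Aqp2, Aqp3, Aqp4, Avpr2, Scnn1b, Scnn1g and Fxyd4, so they are not separate observations. Hsd11b2 and Elf5 are only in the principal cell list. In C57BL/6 the same lists had medians of -0.06 and -0.12, and Aqp2 and Aqp3 stood at -0.24 and -0.31.

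The NRF2 and antioxidant list had a median of 0.31 with 9 of 26 members higher and 1 lower. They included heme oxygenase, Hmox1, at 2.07, the quinone reductase Nqo1 at 1.39, the glutathione-synthesis gene Gclc at 1.26 and the ferritin chain Fth1 at 1.05. Tubular injury genes had a median of 0.37 with 7 of 19 higher and 1 lower, among them clusterin, Clu, at 1.43 and the lipid droplet coat gene Plin2 at 1.24. Immediate early genes had a median of 0.46 with 7 of 14 higher and 1 lower. In that list Egr1 was at 2.09, Fos at 1.79, Ccn1 at 1.45 and Klf4 at -1.70. The glucocorticoid target list had a median of 0.59 with 7 of 14 higher and 1 lower; Cdkn1a and Lcn2, its largest members, also belong to the injury list, while the kinase Pdk4 at 1.29 and the receptor cochaperone Fkbp5 at 0.80 do not. Cell cycle genes had a median of 0.59 with 7 of 13 higher, including the inhibitor Cdkn1a, Prc1 at 1.12, the cyclin Ccnd1 at 0.96 and the thymidylate synthase Tyms at 0.90. Inflammation genes had a median of 0.28, but 3 of 20 were higher and 4 lower, with Ccl5 at 1.12, Cxcl16 at 0.999, Ccl28 at -1.21 and Cxcl9 at -0.87. Of all 9201 expressed genes, 1142 were at least 1.5-fold higher and 1282 lower in FVB/N.

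Cholesterol synthesis had a median of 0.40 with 6 of 16 members higher, including the epoxidase Sqle at 1.44, Pmvk at 1.15, Fdps at 0.87 and Mvk at 0.86, but its median was -0.0167, at percentile 67.9, under the stricter filter. Oxidative phosphorylation had a median of 0.22 with 4 of 32 higher, such as Sdhb at 1.0002, Atp5g1 at 0.76 and Ndufs3 at 0.60. Genes with higher expression in male kidneys had a median of 0.82 with 7 of 12 higher, among them Cyp4a12a, Cyp2d9 at 1.64 and Ugt8a at 1.48, and 1 lower, Kap. The adipocyte list had a median of -0.59 with 6 of 12 lower, including the hormone gene Adipoq at -1.54 and Cidea at -1.45. Markers of the S3 segment had a median of -0.49, with the transporters Slc7a12 at -1.56 and Slc22a7 at -1.22 and the enzyme Kynu at -0.58. Erythroid genes had a median of -0.76, where Hbb-bt was at -1.47, Hbb-b2 at -1.46 and the anion exchanger Slc4a1 at -0.76. That median is the value of Slc4a1, which is also in the list of collecting duct intercalated cell markers. Exocrine pancreas transcripts had a median of -0.53, with Amy2a5 at -1.34, Reg1 at -1.02 and Cela1 at 0.72. Of 50 ranked lists, 15 lay outside the random range, 11 above and 4 below, and cholesterol synthesis, inflammation, cell cycle, S3 and pancreas lay inside it in at least 1 of the 8 alternative settings.

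**Figure D1:**
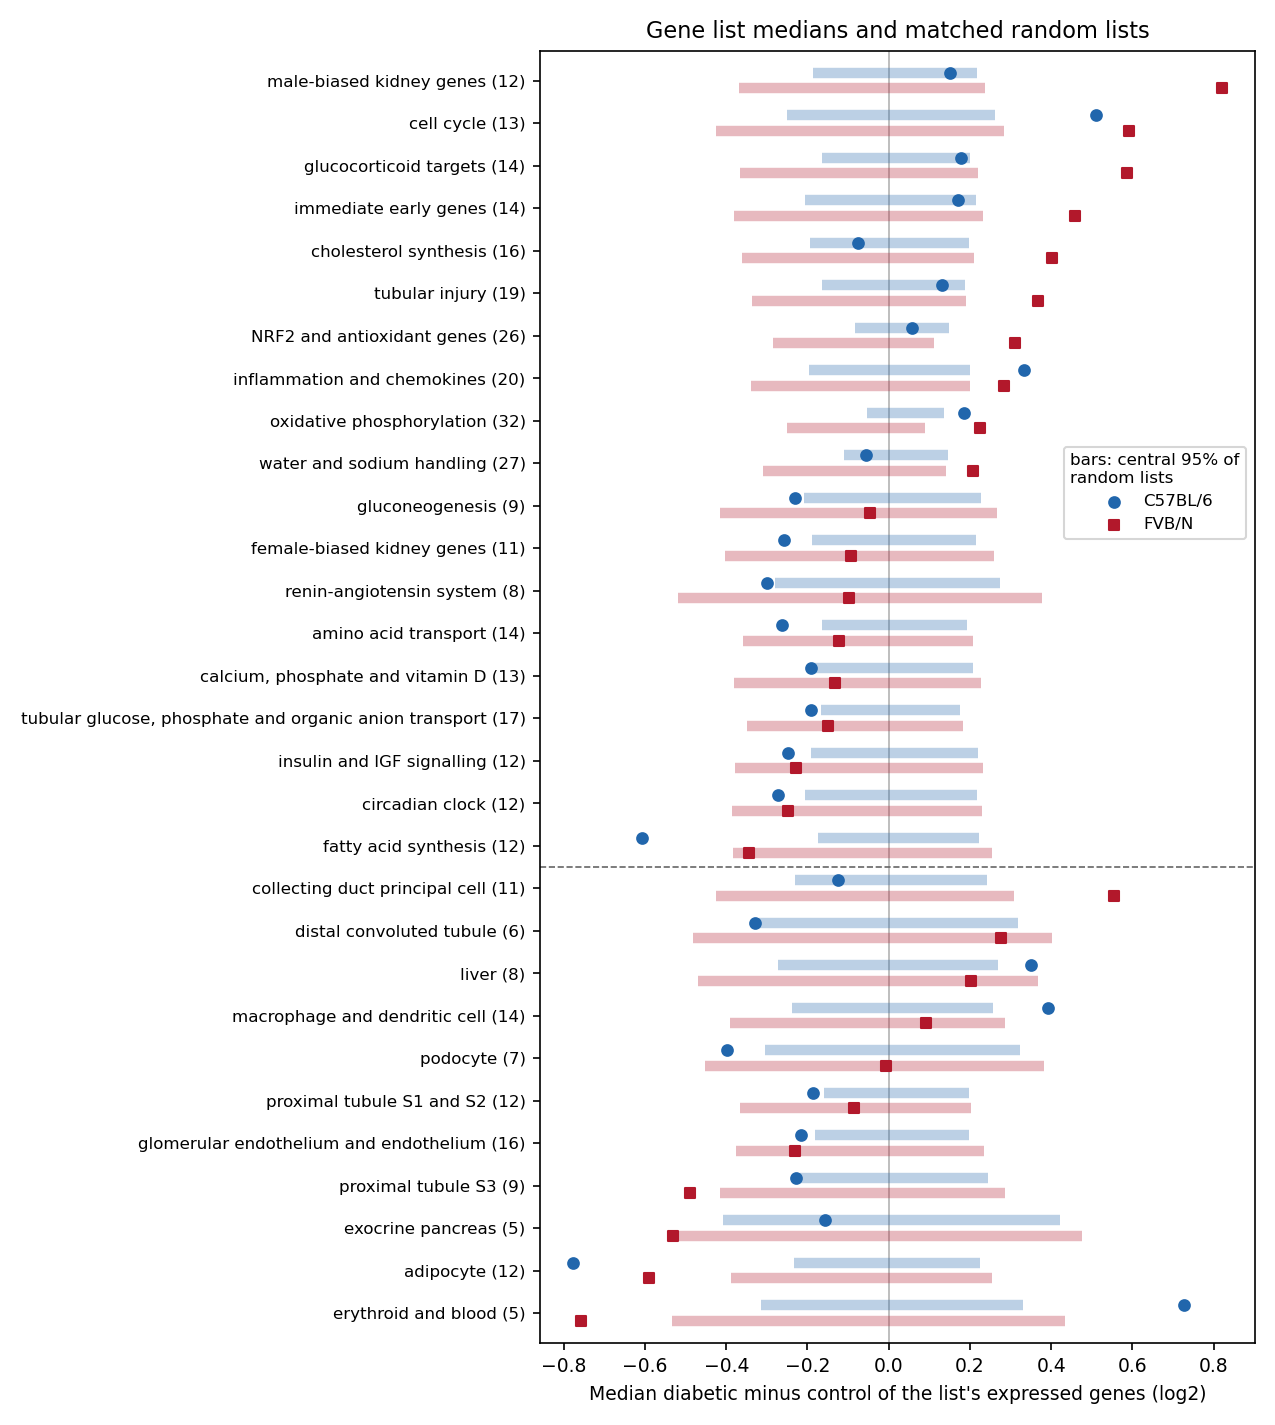
Median log2 difference, diabetic minus control, of gene lists in C57BL/6 and FVB/N on the horizontal axis, with the list on the vertical axis and its number of expressed members in brackets; bars give the central 95% of random lists and the dashed line separates pathway from cell type lists. The adipocyte list lies at -0.78 and -0.59, and the erythroid list at 0.73 and -0.76.

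Several lists central to diabetic kidney work lay inside the random range in both strains. Glycolysis had medians of -0.06 in C57BL/6 and 0.14 in FVB/N, although Pfkp at 2.15 and Aldoa at 1.17 were higher in FVB/N. Fatty acid oxidation and PPAR-alpha targets had a median of -0.03 in each strain, with 7 of 22 members at least 1.5-fold higher in FVB/N, among them Cyp4a12a, Angptl4 at 1.48 and Pdk4. In the list of extracellular matrix and TGF-beta targets, 1 of 28 members was higher and 3 lower in C57BL/6, where Col4a3 stood at -0.84 and Col3a1 at 0.78; in FVB/N 4 were higher and 4 lower. For acid-base genes the medians were -0.11 and 0.05, and Car15 at 1.79, Slc38a3 at 1.40 and Slc4a4 at 1.13 were higher in FVB/N. Glucose-responsive genes had medians of -0.23 and -0.05, with Arrdc4 higher in both strains at 0.68 and 1.39. Heat shock genes had medians of 0.02 and 0.06, with 0 of 9 members higher and 2 lower in FVB/N. Hypoxia targets stood at 0.10 and 0.20, endoplasmic reticulum stress genes at -0.04 and 0.09, and complement genes at 0.05 and -0.33.

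The third comparison asks what the strains share. Fasn was lower in both diabetic libraries, at -2.02 in C57BL/6 and -1.80 in FVB/N, as was Scd1 at -1.62 and -1.10. Cdkn1a was higher in both at 1.52 and 2.99, Lcn2 at 1.25 and 2.88, and the immediate early gene Fos at 1.53 and 1.79, the last from below the expression minimum in C57BL/6 controls. Across genes, which are not independent replicates, the differences of the strains had a Pearson correlation of 0.10, with a bootstrap interval from 0.07 to 0.12, and a Spearman correlation of 0.08. With the stricter filter the Pearson correlation lay above this interval. Within a strain, the differences of 2 probes of a gene correlated at only 0.30 in C57BL/6 and 0.29 in FVB/N. Imprecise probes thus also hold down the correlation between strains, and its low value does not show that the responses are unrelated. At least 1.5-fold in the same direction were 226 genes, 111 higher and 115 lower, where independent strains would give 70.1 and 81.4. In opposite directions were 139 genes, 60 higher in C57BL/6 and lower in FVB/N and 79 the other way, where independent strains would give 78.7 and 72.5. Of those in the same direction, 15 were at least 2-fold higher in both strains and 13 at least 2-fold lower in both.

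Other genes higher in both were Serpina10 at 2.04 in C57BL/6 and 1.65 in FVB/N, Ch25h, which hydroxylates cholesterol, at 1.20 and 1.70, and S100a9, a subunit of calprotectin, at 1.21 and 1.20. Sigirr, which damps interleukin and toll-like receptor signalling, stood at 1.18 and 1.17; S100a9 and Sigirr too were below the minimum in C57BL/6 controls. Spink8, of a family of peptidase inhibitors, was at 1.13 and 1.31, Prc1 at 1.67 and 1.12, and Snrnp25 of the minor spliceosome at 1.20 and 1.07. Havcr1 was higher in both as well, by 1.74 and 0.93, from below the minimum in both controls. Lower in both were the brown-fat genes Cox8b at -1.60 and -2.83, Ucp1 at -1.51 and -5.27, and Cidea at -1.81 and -1.45. The same held for Slc22a7 at -1.16 and -1.22, Cd180 at -1.81 and -1.13, and Npr2, a receptor for natriuretic peptides, at -1.03 and -1.31. Spats2l was at -1.26 and -1.61, but at -0.64 and -0.99 with probes averaged, and Spns3 at -1.10 and -1.61. The lists outside the random range in both strains on the same side were adipocyte, S3 segment, oxidative phosphorylation, inflammation and cell cycle. Of these 5, adipocyte and oxidative phosphorylation lay outside it in both strains in all 8 alternative settings and the others did not, S3 for example being at percentile 13.3 in FVB/N without a filter. The fatty acid synthesis list had a median of -0.34 in FVB/N, with 5 of 12 members lower, and lay inside it there.

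**Figure D2:**
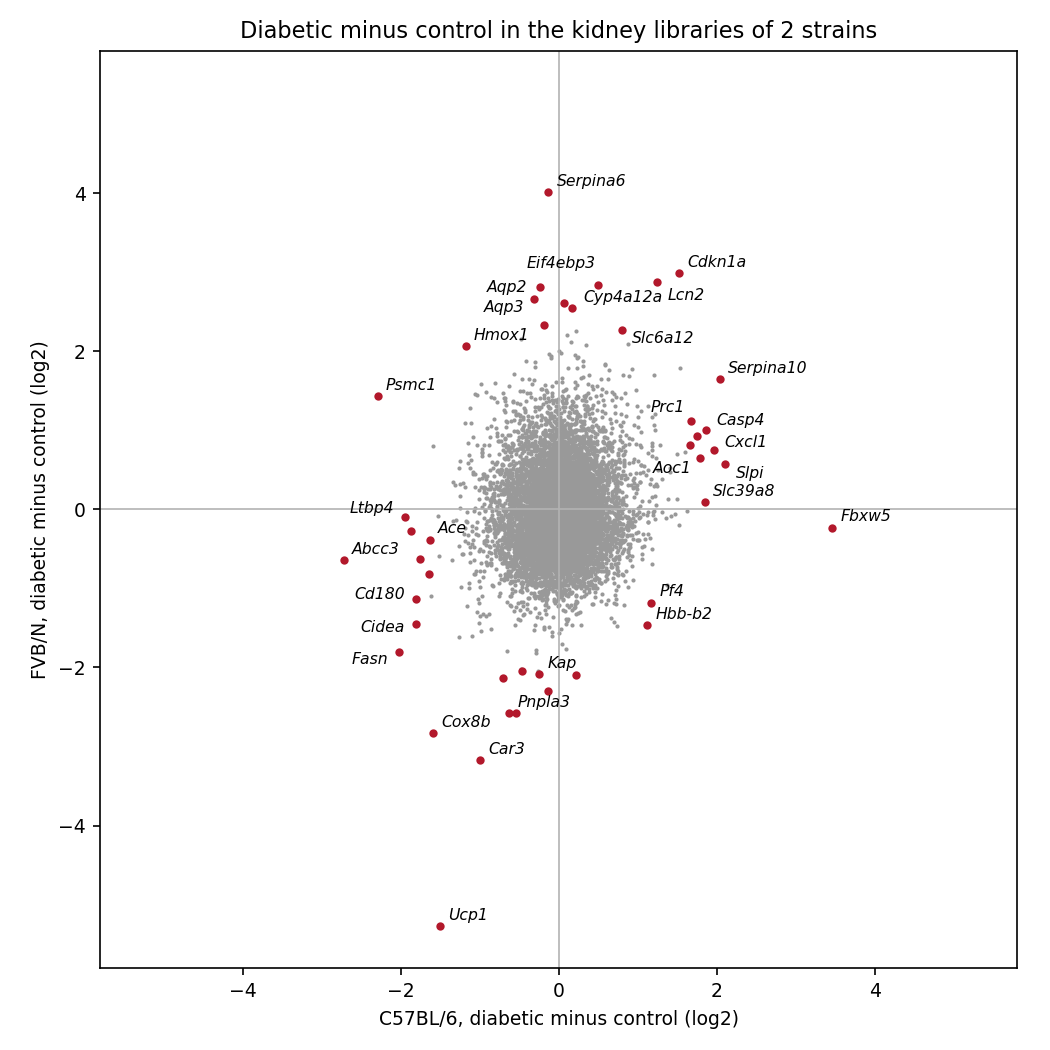
Log2 difference of diabetic minus control in C57BL/6 on the horizontal axis and in FVB/N on the vertical axis, 1 point per expressed gene; red points are genes named by rule, of which some carry their symbol. The correlation across 9201 genes is 0.10, and Fasn, at -2.02 and -1.80, lies low on both axes.

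The fourth comparison asks where the strains' differences part. Aqp2 and Aqp3 were 3.05 and 2.97 log2 further up in FVB/N than in C57BL/6, and Serpina6 was 4.14 further up. Aqp3 and Serpina6 rose from below the expression minimum in FVB/N controls, and Serpina6 was below it in both C57BL/6 libraries too. Hmox1 was lower in the C57BL/6 diabetic library, at -1.18, and higher in FVB/N, at 2.07. Psmc1 was likewise lower in C57BL/6, at -2.29, and higher in FVB/N, at 1.43. Fbxw5 was higher in C57BL/6 and at -0.23 in FVB/N, a difference of -3.69. Ucp1 differed by -3.76, being lower in both strains, with its FVB/N diabetic value below the expression minimum. Hbb-b2, a globin, and Pf4, the platelet factor, were higher in C57BL/6 and lower in FVB/N, with differences of -2.58 and -2.35. By this measure 560 genes were at least 2-fold further up and 522 at least 2-fold further down in FVB/N, and after loess centring on intensity 681 and 394. These counts carry the noise of all 4 libraries. The standard deviation of a single probe's value was 0.58 log2 here, against 0.33 in C57BL/6 and 0.47 in FVB/N. The values of 2 probes of a gene correlated at only 0.21, so the counts do not give the number of genes that respond differently.

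Lists that lay further up in FVB/N included the distal convoluted tubule at 0.80, with 4 of 6 members at least 1.5-fold further up, the renin-angiotensin list at 0.48 and glucocorticoid targets at 0.47. Interferon-stimulated genes stood at 0.44, principal cell markers at 0.42 and water and sodium handling at 0.38. For male-biased genes the value was 0.48, for glycolysis 0.33, for cholesterol synthesis, acid-base and fatty acid synthesis 0.27, for fatty acid oxidation 0.23 and for NRF2 targets 0.14. Below the random range were fibroblast markers at -0.71, with the matrix genes Lum at -1.41, Dpt at -1.29 and Col3a1 at -1.25, and erythroid genes at -1.21. In total 13 lists lay above the range and 2 below. Interferon-stimulated genes, glycolysis, acid-base genes, fatty acid oxidation and fibroblast markers lay inside the random range in each strain's own diabetes comparison. Lists of this comparison were not ranked again under the alternative settings.

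The last comparison asks how the strains differ with and without diabetes. Rnase4, a secreted ribonuclease, was 6.54 log2 higher in FVB/N than in C57BL/6 controls and 5.74 higher in diabetics. The antigen presentation genes H2-T23 and H2-Eb1 were lower in FVB/N, at -4.41 and -4.76 in controls and -4.42 and -4.25 in diabetics. The list of antigen presentation genes as a whole lay inside the random range, with medians of -0.10 in controls and -0.12 in diabetics. Of its 13 members, 5 were at least 1.5-fold lower and 1 higher in controls, and 5 lower and 3 higher in diabetics. Ttr was also lower in FVB/N, at -5.40 and -5.98. In controls 144 genes were at least 2-fold higher and 239 at least 2-fold lower in FVB/N. In diabetics the counts were 513 and 453, and with the stricter filter 241 and 282. The comparison in diabetics includes the FVB/N diabetic library, which lay farthest from the others. The standard deviation of a single probe's difference was 0.55 log2 there, against 0.39 in controls. The larger counts in diabetics therefore do not show by themselves that diabetes widens the strain differences. At least 2-fold apart in both conditions were 56 genes higher and 146 lower in FVB/N. The strain differences in controls and diabetics, which rest on separate libraries, had a Pearson correlation of 0.43 and a Spearman correlation of 0.20 across genes.

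Also higher in FVB/N, in controls and diabetics respectively, were Abhd1 at 4.75 and 4.05, the estrogen-regulated gene Greb1 at 4.35 and 3.01, and the lipid kinase Pik3c2g at 3.84 and 3.39. The phosphodiesterase Gdpd3 was at 2.90 and 3.12, the lipid flippase Atp10d at 2.96 and 2.36, and Psmc3ip, which acts in recombination, at 2.81 and 2.22. The steroid dehydrogenase Hsd3b2 stood at 2.38 and 3.05, and the transcription factor Cebpd at 2.28 and 2.38. Lower in FVB/N were the selenocysteine tRNA partner Trnau1ap at -5.55 and -6.001 and the glutathione transferase Mgst1 at -4.95 and -4.34. Securin, Pttg1, stood at -4.49 and -5.29, the replication helicase subunit Mcm6 at -4.49 and -4.51, and Spink8 at -4.38 and -4.20. Rbm14 was at -4.20 and -3.77, and the Fc receptor chain Fcer1g at -3.70 and -3.80. The lower strain's value was below the expression minimum for Rnase4, Greb1, Trnau1ap, Mcm6, Rbm14 and Fcer1g in both conditions and for H2-Eb1 in controls, so the size of these differences is uncertain. Where probes were averaged, Rnase4 came to 5.49 and Abhd1 to 3.90 in controls. In controls and diabetics, Mcm6 came to -1.62 and -1.80, Rbm14 to -2.10 and -2.05, Greb1 to 2.26 and 1.61, Cebpd to 1.23 and 0.90, and Hsd3b2 to 1.68 and 1.58.

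Among lists, liver transcripts were lower in FVB/N at -0.91 in controls and -1.07 in diabetics, led by Ttr, Apoa2 at -2.78 and Serpina1a at -2.75 in controls. Interferon-stimulated genes had a median of -0.39 in controls, with Ifit3 at -1.34 and Bst2 at -0.99. T and NK cell markers stood at -0.45, with Cd8b1 at -1.23. The matrix list had a median of -0.09, in which Col1a2 at -3.10, below the minimum in FVB/N, and Sparc at -2.72 were far below the other members. In the erythroid list, at 0.76, Hbb-b2 was at 4.13 and Hbb-bt at -1.93. Amino acid transport lay higher in FVB/N in both conditions, at 0.26 and 0.34. In diabetics the distal convoluted tubule stood at 0.74, where the controls had -0.40, the renin-angiotensin list at 0.55 and fibroblast markers at -0.58. In each condition 14 lists lay outside the random range, and these were not ranked again under the alternative settings.

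**Figure D3:**
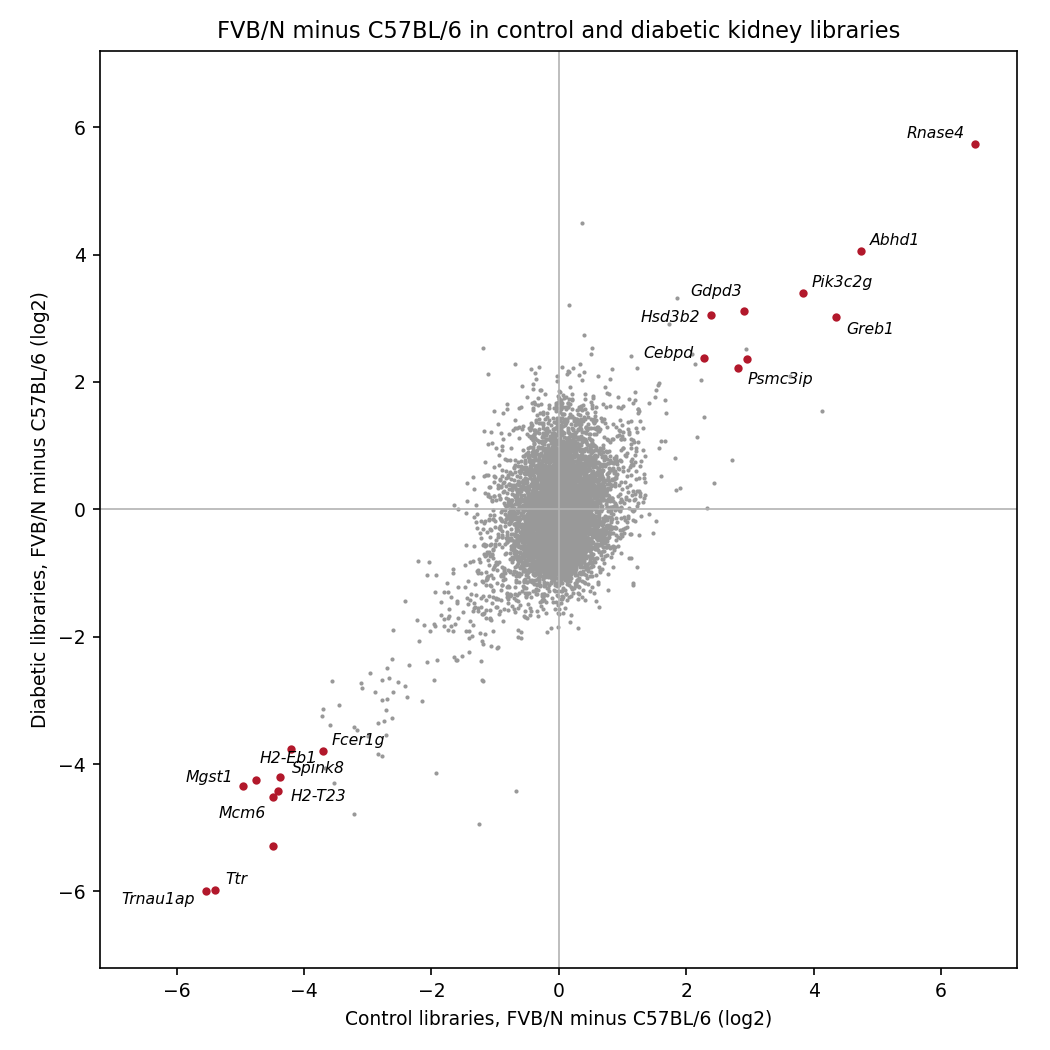
Log2 difference of FVB/N minus C57BL/6 in controls on the horizontal axis and in diabetics on the vertical axis, 1 point per expressed gene; red points are genes named by rule, of which some carry their symbol. Rnase4 lies at 6.54 and 5.74, and across genes the Pearson correlation is 0.43 and the Spearman correlation 0.20.

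The Y-chromosome genes Eif2s3y, Uty, Kdm5d, Usp9y and Zfy1 gave no clear signal in any library. Whether these probes work is unknown, so the sex make-up of each library, which also bears on the male-biased and female-biased lists, is unknown beyond the series text's mention of both sexes. The Usp9y probe in the C57BL/6 diabetic library, at 5.53, had the highest value of these genes, at percentile 51.7 of all probes. Nnt, which carries a deletion in some C57BL/6 substrains, and Hc, a complement gene that differs between inbred strains, were also at or near background in all 4 libraries, so neither could check the strain labels.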

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

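The tests of adipocyte-restricted markers, of whether those markers moved alike, of probe noise as the only cause, and the centring on gene length were chosen only after the results they address had been seen.

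The globin Hbb-b2, heme oxygenase Hmox1, platelet factor Pf4, the proteasome gene Psmc1 and the erythroid list stood out because their diabetes differences had opposite signs in the 2 strains. Hbb-b2 was at 1.12 in C57BL/6 and -1.46 in FVB/N, a difference of -2.58, and Pf4 at 1.17 and -1.18, a difference of -2.35. The erythroid list had medians of 0.73 and -0.76 and a median difference of -1.21. Its FVB/N median is the value of Slc4a1, which is also in the list of collecting duct intercalated cell markers. Hmox1 was at -1.18 and 2.07, a difference of 3.24, and Psmc1 at -2.29 and 1.43, a difference of 3.72. None of these differences was tested, since each strain has 1 diabetic and 1 control library. No explanation was tested for them either.

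Adipocyte genes were lower in both diabetic libraries, and fatty acid synthesis genes were lower in C57BL/6. Of 6 adipocyte-restricted markers a share of 0.833 lay below the median of all genes in both strains, but all 6 belong to the adipocyte list, so the share restates the pattern and leaves less attached fat tissue undecided. In C57BL/6 all 6 were at least 1.5-fold lower, with a median of -0.998 and a median absolute deviation of 0.09, Cidea at -1.81 and Ucp1 at -1.51 lying further down; in FVB/N 4 were, with a median of -1.49 and a deviation of 1.49, from Ucp1 at -5.27 to Cidec at 0.13. The fatty acid synthesis median in C57BL/6 exceeded the marker median by 0.39, which does not exclude less fat alone for the list as a whole, but Fasn at -2.02, Scd1 at -1.62 and Acaca at -1.35 lay below that median, and tubule cells also make these transcripts. Less attached fat stays open, as do lower transcript levels per adipocyte and a lower lipid synthesis in the tubule, with diabetes itself as the untested biological cause.

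More genes were at least 2-fold apart in FVB/N, 574, than in C57BL/6, 186, a ratio of 3.09 that ran from 2.11 at a threshold of 1.5-fold to 5.19 with an offset of 16 and 6.70 with the stricter filter. An average shift with intensity is argued against as the cause, since the ratio was 3.35 after loess centring on intensity. So is an average shift with gene length, since the ratio was 3.25 after centring on length. Centring leaves the spread of the differences in place, so a spread that varies with intensity or length was not tested. Noise of single probes on an FVB/N array is argued against as the only cause: the covariance of the differences of 2 probes of a gene, to which such noise does not contribute, was larger in FVB/N by 0.0435, with a standard error of 0.0106. Whether such noise contributes cannot be told apart. The differences of 2 probes of a gene lay a median of 0.43 apart in FVB/N and 0.26 in C57BL/6. Their correlation was low in both strains, 0.29 in FVB/N and 0.30 in C57BL/6, and differed by only -0.0089 with a standard error of 0.0375. Probes below the expression minimum spread alike, by 0.27 and 0.25. A difference in RNA quality or dissection of the FVB/N diabetic library, which by median difference lay farther from the other 3 (0.23 to 0.24) than they did from each other (0.17 to 0.20), the authors' normalization, and a larger response to diabetes in FVB/N stay open, and with 1 library per group none of them was tested.

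In FVB/N against C57BL/6, 51 probes were at least 4-fold lower in both conditions and 18 at least 4-fold higher. Sequence variants under the probes might lower binding in FVB/N, if probes were designed on the C57BL/6 sequence. Of 12 probes with a further expressed probe of the same gene, 3 were contradicted by it, being less than 1.5-fold apart in both conditions, a share of 0.25 with an exact Clopper-Pearson 95% interval from 5.49% to 57.2%, against 1 of 8 among the higher probes. The further probe was at least 1.5-fold apart the same way in both conditions for 5 of the 12 lower and 7 of the 8 higher probes, which is the direction that variants would give. The probes are too few to decide. For single genes such as Trnau1ap, Mgst1, H2-T23 and H2-Eb1 a variant and a difference in expression therefore cannot be told apart.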

How the results depend on the processing

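The centring on gene length was chosen after the data had been seen. Some agreement under the alternatives was fixed in advance. The filters leave a named gene's value unchanged, and quantile normalization barely changes libraries that already have near-identical distributions. Named genes were also picked for large differences, which makes a reversal unlikely. Median centring shifts all genes of a comparison alike, so it leaves list percentiles unchanged and is no separate check of them. Of 282 list medians under the alternatives, 261 stayed within 1 standard deviation of their random lists, 19 moved further and 2 reversed; of 895 values of named genes, 857 stayed within 1 standard deviation of the differences of single probes, 38 moved and 0 reversed; of 77 counts and summaries, 62 stayed within 1.5-fold, or the bootstrap interval for the correlation, and 15 moved. The reversed values were the C57BL/6 calcium, phosphate and vitamin D list, at 0.0097 without a filter, and the FVB/N cholesterol synthesis list, at -0.0167 under the stricter filter; the cause was not tested. With the stricter filter, which tests fewer genes, 43 genes were at least 2-fold apart in C57BL/6, 288 in FVB/N, 435 in the difference of effects, 164 between controls and 523 between diabetics. There the correlation of the strains' differences was 0.16, 13 lists lay outside the random range in C57BL/6 and 19 of the 40 genes with the largest diabetes differences were again among the 10 largest in their direction and strain; 31 named genes and several lists of few members had no value. An offset of 16, which shrinks differences of weak genes, gave 79 genes in C57BL/6 and 715 in the difference of effects. By construction, the 1.5-fold threshold gave more genes: 1149, 2424, 3136, 1200 and 2904 in the order above. Centring moved the balance of directions in FVB/N, from 65.0% higher to 76.8% with loess on intensity and 75.9% with gene length, and in the difference of effects from 51.8% to 63.3% and 63.6%. Between diabetics, 53.1% of the genes were higher in FVB/N, against 60.6% with loess on intensity and 46.1% with the stricter filter, where more were lower. The stricter filter moved the balance in C57BL/6 from 51.1% to 32.6% and in FVB/N from 65.0% to 55.6%. The cause was not tested. Of the lists outside the random range, 13 of 21 in C57BL/6 and 10 of 15 in FVB/N were outside in all 8 settings where they had a value. Those that were not were, in C57BL/6, gluconeogenesis, renin-angiotensin, inflammation, circadian clock, insulin and IGF, calcium, S3 and distal convoluted tubule, and in FVB/N cholesterol synthesis, inflammation, cell cycle, S3 and pancreas. Signal near background limits the folds of genes such as Havcr1 and Serpina6, since no detection calls were used.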

Other observations

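Probes without an annotated gene also differed between libraries. Of 1477 such probes above the expression minimum, 13 were at least 2-fold higher and 17 at least 2-fold lower in the C57BL/6 diabetic library, and 70 higher and 34 lower in FVB/N.

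Cdkn1a, Ccng1 and Chek2, which take part in the response to DNA damage, were higher in the C57BL/6 diabetic library, at 1.52, 1.41 and 1.501; Ccng1 and Chek2 were chosen after their values were seen, and Chek2 was below the expression minimum in the control library, so the size of its difference is uncertain. A list of 20 p53 targets that includes them had a median of 0.29 in C57BL/6, with 7 members at least 1.5-fold higher and 1 lower, at percentile 99.8 of random lists. In FVB/N the median was 0.08, with 4 higher and 3 lower, at percentile 87.6. A p53 response in both strains is a candidate explanation. Without these 3 genes the list lay inside the random range in both strains, at percentile 97.3 in C57BL/6, near its upper end, and at 48.1 in FVB/N, near the middle. The C57BL/6 list thus lay outside only with the genes chosen after they were seen, and the test leaves a p53 response undecided there. In FVB/N the remaining targets had a median of -0.12, against -0.11 for the random lists, so as a set they were not higher. The prediction, written before this test, counted a median at or below the middle in either strain against a response in both. FVB/N met that by a narrow margin. Cdkn1a is also a target of glucocorticoid signalling and a marker of tubular injury, and the values do not separate these.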
